A study of Danio rerio with 6 samples.

How the data were processed

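The data are whole-number counts per gene for 6 liver libraries, deposited as a single table of 32520 Ensembl gene identifiers. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was captured on poly-T beads, and cDNA was primed with random hexamers. The counts the authors deposited came from HISAT2 alignments per the file headers. The build was GRCz11, also called danRer11, per the submitters' processing notes. The HISAT2 version, the counting tool, its strand setting and the annotation release are not given in the sources used here, so overlapping and antisense genes cannot be told apart, and near-identical copies may share reads. No filtering or scaling before deposit is recorded in the file headers. Groups were taken from the treatment labels, which name fresh sperm as the control, and all libraries carry a single batch label. The labels give fresh sperm to the titles F1 to F3 and cryopreserved sperm to C1 to C3. The letters alone can also be read as frozen and control, and if letters and labels were crossed every direction given here would reverse.

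Names came from a table of gene identifiers and symbols, which matched 29201 of the 32520 identifiers. Many of its symbols are in capitals and can stand for several zebrafish genes. Symbols of the fixed lists were therefore matched exactly, then through a short hand-written table, then in capitals, then without a copy number or a closing a or b. This matching rule was set after the table was seen, and it matched 1473 of 1578 list symbols. No genome was used here.

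Of 21810 genes with any count, 12674 passed edgeR's filterByExpr and were tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, a quasi-likelihood fit of group, two-sided tests of cryopreserved over fresh, and Benjamini-Hochberg adjustment with a threshold of 0.05. The standard error of a log2 change is its size over the square root of F. CPM in the text are TMM-normalised, except those of vitellogenin and zona pellucida genes, the fold of ESR1 and nots over the other libraries, and the vitellogenin plot, which use all counts. The biological coefficient of variation was 0.413. Lists were tested with camera and fry of limma 3.58.1 on log2 CPM with a prior count of 2, where at least 5 members were tested, which held for 42 of 46 lists. A fold against a group at 0 is a lower bound against 3 counts over the group, and ratios with 1 to 3 counts carry a 95% counting interval, which covers counting error only.

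The genes named follow a rule fixed before the data were examined. It takes the 12 largest changes each way among named genes past the threshold with at least 1 CPM and no overlap, the 4 members of smallest p in each list past the camera threshold, a fixed set of liver genes, and the 5 most abundant genes. Of the list members so chosen, a part is printed, and values of some genes the rule takes are not reported here. Any other gene is said to have been chosen after its values were seen.

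The procedure was tested on simulated counts for this comparison of 3 against 3, over 12386 genes. It recovered 0% of genes changed by 1 on the log2 scale, 56% at 2, 86% at 3 and 98% at 5, with 7 false calls among 127. Changes of 1 on the log2 scale were thus out of reach at this spread, and sizes between 1 and 2 were not simulated. The changed genes were drawn from those with a mean of at least 5 CPM. Libraries of a group differed only by random spread in the simulation. In the real data the smallest change called was 1.24 on the log2 scale. Depth differed by group, with the shallowest libraries, 8277183 and 10409786 counts, both in the cryopreserved group. No pair of libraries within a group agreed within sampling noise, with chi-square per degree of freedom from 53.2 to 442.8.

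Alternatives fixed beforehand were other size factors, other low-count filters, DESeq2 1.42.0, limma-voom, a replicate block, each library left out, abundant genes left out, other thresholds and other list tests. After the data were seen, cryo replicates 2 and 3 were left out together and all libraries were thinned to the shallowest total. The first of these leaves 1 cryo library, which is assumed to vary like the fresh ones. A check of whether changed genes neighbour each other was tried by 2 routes, and neither could be used. By symbol and synonym in a RefSeq table of the GRCz12tu assembly, 75.3% of the changed genes had a position (70.5% by symbol alone), under the 80% set as the minimum. The order of rows in the count table was tried next: 62 changed genes lay within 5 tested rows of another, against a mean of 45.5 and a highest of 73 in 2000 shuffles. That order keeps chromosomes together (96.7% of adjacent placed rows) but not positions, with a median of 385 genes between adjacent rows, so this count is no measure of neighbourhood and nothing is drawn from it. Figures were drawn with matplotlib 3.10.9.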

Results

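Liver RNA from zebrafish offspring was compared between fish sired with cryopreserved sperm and fish sired with fresh sperm, a question that the series title frames as long-term effects of sperm cryopreservation. The 6 poly-A RNA-seq libraries came from wild-type fish of the AB laboratory strain, 3 in the fresh sperm group (fresh replicates 1 to 3) and 3 in the cryopreserved sperm group (cryo replicates 1 to 3). The labels call them biological replicates but give neither sex nor age, nor whether a library held 1 fish or a pool, so p-values measure the spread between these libraries. Total counts were 17046138, 17606733 and 16885619 in fresh replicates 1 to 3, and 16146121, 8277183 and 10409786 in cryo replicates 1 to 3. Gene symbols are given as the name table lists them, many in capitals, and an Ensembl identifier stands beside a symbol that several genes share.

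In the cryopreserved sperm group, 6 of 37 genes of fatty acid oxidation and the growth factor gene IGF1 fell, while 11 of 26 pancreatic genes and the antigen presentation genes cd74a and cd74b rose. Whether the pancreatic RNA came from liver cells or from pancreatic tissue in the dissected liver is not settled. In all, 251 of 12674 tested genes changed by edgeR's quasi-likelihood test at an adjusted p under 0.05, 129 of them higher and 122 lower in the cryopreserved sperm group. The changes that passed were large, with a median size of 3.06 on the log2 scale, and 199 of the 251 genes differed by more than 4-fold. The 3 values of each group did not overlap for any of the 251 genes. Over all tested genes 24.6% had no overlap, where chance gives 10%. The count rested on few libraries: it was 79, 47 and 32 without fresh replicates 1, 2 and 3, and 873, 149 and 119 without cryo replicates 1, 2 and 3. The 873 came from cryo replicates 2 and 3, where vitellogenin RNA made up 17.4% and 12.4% of counts. In fresh libraries it made up at most 6.04e-04%. Without cryo replicate 1 the group is thus not separated from whatever brought the vitellogenin RNA. With cryo replicates 2 and 3 both left out, an alternative added after the data were seen, 109 genes passed, 60 of them among the 251. That fit has a single cryo library, so the fresh libraries gave all of the spread and cryo replicate 1 was assumed to vary like them, and its count is not comparable with that of 3 against 3.

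Libraries of the fresh group resembled each other more than those of the cryopreserved group did. Pearson correlations of log2 CPM across genes ran from 0.936 to 0.954 within the fresh group, from 0.875 to 0.902 within the cryopreserved group and from 0.827 to 0.891 between groups. Genes are not independent replicates, so no test was made of these. The leading principal component held 61.3% of the variance of the 500 most variable genes and separated the groups, with fresh libraries from -42.1 to -34.6 and cryo libraries at 19.4, 52.8 and 42.7. On the next component, with 15.4% of the variance, cryo replicate 1 stood at -42 and the other cryo libraries at 12.8 and 15.3.

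Among the largest decreases were genes with no count at all in the cryopreserved sperm group. PHF21A (ENSDARG00000006878), a histone-binding repressor subunit, had 27.69, 33.10 and 36.49 CPM in the fresh libraries and 0 in every cryo library, at least 341-fold lower against a floor of 3 counts over the group (adjusted p = 0.00253). The carbonyl reductase gene cbr1l fell from 74.5 ± 13.3 CPM (SD, n = 3) to 2 counts in all, a ratio of 1180 with a counting interval of 327 to 9750 (edgeR adjusted p = 0.00104). GAD1 (ENSDARG00000093411), which encodes a glutamate decarboxylase, was at least 56.3-fold lower, the potassium channel gene kcng4b at least 49.0-fold, the histamine receptor gene hrh3 at least 37.1-fold and TENM4 at least 34.3-fold. ZNF592, FBXO31, the sulfotransferase gene sult1st5 and BAHD1 were at least 27.4, 26.6, 21.2 and 12.5-fold lower. PIK3C2A, a phosphoinositide kinase gene, changed by -6.66 ± 0.65 on the log2 scale (SE) and the neuroligin gene nlgn4xa by -6.67 ± 0.88. With cryo replicate 1 as the single cryo library, where the fresh libraries gave all of the spread, 4 of these 12 genes passed (PHF21A, cbr1l, hrh3 and PIK3C2A). The other 8 missed the threshold: FBXO31 and GAD1 (adjusted p = 0.0522 and 0.0524), TENM4 and nlgn4xa (0.0612 each), ZNF592 (0.0641), sult1st5 (0.0943), kcng4b (0.0964) and BAHD1 (0.108), at log2 changes from -9.49 for GAD1 to -7.34 for BAHD1.

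The largest increases included genes that were silent or nearly so in fresh libraries. The chemokine receptor gene cxcr3.3 had no count in the fresh group and 2.98, 17.31 and 6.77 CPM in the cryo libraries, at least 126-fold higher (edgeR adjusted p = 0.0284). TENM2 (ENSDARG00000011171) was at least 112-fold higher, and MAST2 and nlrc9 at least 43.5-fold. Genes with 1 to 3 counts in the fresh group were cgref1 (ratio 476, interval 84.8 to 18868), PAFAH1B3 (ratio 289, interval 51.2 to 11490), tmem176l.2 (ratio 177), IDUA (ratio 119) and tor1l3 (ratio 89.3). The gene pof1b rose from 0.12, 0.11 and 0.12 CPM to 26.20, 15.46 and 25.09, a log2 change of 7.49 ± 0.41 (adjusted p = 0.00104). The gene sona rose by 5.89 ± 0.48 and INHBA (ENSDARG00000024759), which encodes an activin subunit, by 5.88 ± 1.09. INHBA missed the threshold by limma-voom (0.111) and after thinning (0.0669). With cryo replicate 1 as the single cryo library, TENM2, cgref1, PAFAH1B3, pof1b and sona passed, and MAST2 was too low to be tested. In that fit tmem176l.2, tor1l3, IDUA, cxcr3.3, nlrc9 and INHBA missed the threshold, at log2 changes of 7.25, 6.47, 6.46, 8.69, 7.92 and 4.03. With all libraries these were 6.89, 6.23, 6.34, 9.96, 8.32 and 5.88. Calls of named genes depended on the libraries: of 50 named genes past the threshold, 15, 9 and 8 stayed past it without fresh replicates 1, 2 and 3, and 50, 28 and 23 without cryo replicates 1, 2 and 3. With cryo replicate 1 as the single cryo library 33 of the 50 calls were lost. Of 75 named genes not past the threshold, 50 passed by DESeq2 and 28 by edgeR without the low-count filter, so those given below as not passing missed it in edgeR with its filter. By DESeq2 these included prss1 (adjusted p = 1.93e-04), IRS2 (3.15e-05), MT-ND1 (7.93e-05), MT-ND2 (4.68e-05), MT-ND5 (3.58e-04), ctss2.2 (1.07e-04), irg1l (0.0103), SQLE (0.0486), apoeb (0.0128), FASN (0.0164), tfa (1.47e-04) and apoa2 (0.0487), and of these prss1 (0.0163), IRS2 (0.00751), ctss2.2 (0.00982), irg1l (0.00866) and SQLE (0.0212) also passed without the filter.

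**Figure D1:**
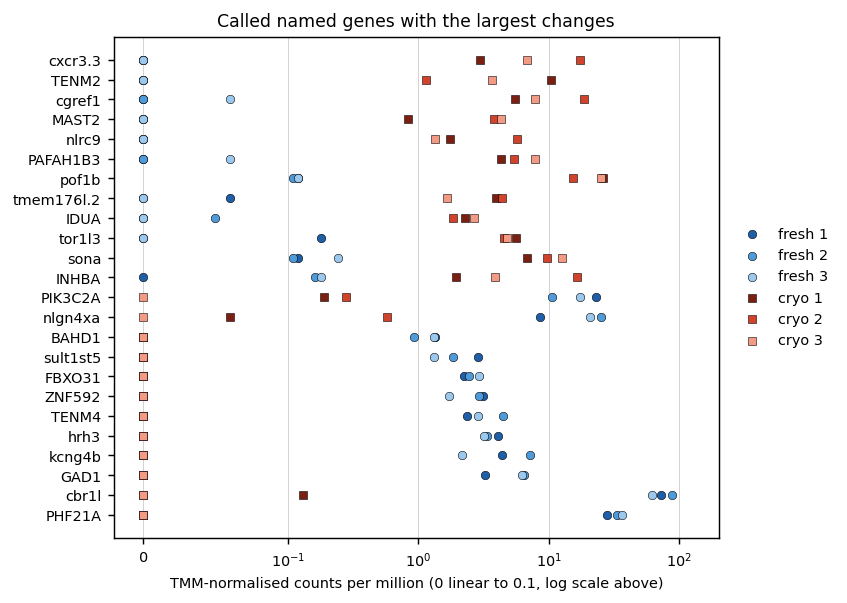
TMM-normalised CPM (x axis, linear to 0.1 and log above) of the 12 named genes with the largest increase and the 12 with the largest decrease among those past the threshold. Circles are the 3 fresh libraries and squares the 3 cryo libraries, and the groups do not overlap for any gene, as for PHF21A at 27.69 to 36.49 against 0.

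Of 42 gene lists fixed before the data were examined and large enough to test, 20 passed limma's camera test with its preset correlation of 0.01, 10 upward and 10 downward. None of the 20 passed with a correlation estimated per list, so each list is given with that p. By limma's fry test, which asks whether a list's own genes move, 2 lists passed in one direction (fatty acid oxidation and heat shock response, downward) and 33 passed for change in either direction. With cryo replicate 1 as the single cryo library, assumed to vary like the fresh ones, the camera adjusted p was 0.132 for apolipoproteins and for xenobiotic metabolism, 0.148 for gluconeogenesis, 0.0522 for amino acid catabolism and for nuclear oxidative phosphorylation, 0.0672 for heat shock and 0.0565 for immediate early genes. In the same fit, genes named below from the lists that lost their own call kept their direction. Their log2 changes were -1.69 for IGF1, -1.81 for IGFBP5, -1.85 for PPARGC1A, -1.67 for HADHA, -1.35 for CRAT and -2.51 for PDK2. MMUT had -1.53, BCKDHA -1.17, GPT -1.85, mt-atp8 -1.31, ugt5a1 -2.625, ugt2a6 -4.07 and hamp -3.10. Upward, cela1.3 had 3.44, the 2 called copies of MFAP4 3.21 and 2.43, cd74a 1.35, cd74b 1.37 and cfbl 2.61. The genes amy2a, CEL, ela3l, eif4ebp1, gstt1b, POSTN and RPL12 passed.

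Genes of mitochondrial fatty acid oxidation were lower as a group. The list had a median log2 change of -0.87, with 34 of 37 tested genes negative and 6 past the edgeR threshold, all lower (22 lower when adjusted over the list alone; camera adjusted p = 1.21e-11). With an estimated correlation the adjusted p was 0.517, and over the 12 alternatives of the camera test it ranged from 2.33e-12 to 0.517. The shift of a list in a library, here and below, is the mean over its members of log2 CPM minus the fresh mean. For this list it was -0.98, -1.07 and -0.90 in cryo replicates 1, 2 and 3. PPARGC1A, a coactivator of mitochondrial gene programmes, fell by 2.07 ± 0.32 on the log2 scale, from 10.6 ± 2.89 to 2.49 ± 0.321 CPM (adjusted p = 0.0251). The beta-oxidation subunit gene HADHA changed by -1.70 ± 0.30 and the carnitine acetyltransferase gene CRAT (ENSDARG00000016545) by -1.65 ± 0.27. PDK2 (ENSDARG00000020876), a kinase gene whose product restrains pyruvate oxidation, fell from 113 ± 29.9 to 26.4 ± 9.51 CPM.

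Transcripts encoded in the mitochondrial genome moved the same way. All 13 were negative, with a median of -1.10, 1 past the threshold and 9 adjusted over the list alone (camera adjusted p = 1.06e-08; adjusted p = 0.517 with an estimated correlation, and 3.23e-09 to 0.517 over the alternatives). The change of mt-atp8 was -1.63 ± 0.31 (edgeR adjusted p = 0.0465, and 0.0513 with RLE factors, 0.0563 with upper-quartile factors, 0.0552 by limma-voom, 0.0522 with abundant genes left out and 0.05005 after thinning), while MT-ND1, MT-ND2 and MT-ND5 had -1.40, -1.44 and -1.61 without passing. Nuclear genes of oxidative phosphorylation shifted less, with a median of -0.39 over 75 genes and 0 past the threshold (camera adjusted p = 0.00316; adjusted p = 0.80 with an estimated correlation, and 3.09e-05 to 0.80 over the alternatives). Without fresh replicate 1 that list missed the threshold, at a camera adjusted p of 0.089. Its shift was 0.16, -0.23 and 0.07 in fresh replicates 1, 2 and 3. In cryo replicates 1, 2 and 3 it was -0.23, -0.21 and -0.29, so fresh replicate 2 was as low as cryo replicates 1 and 2.

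Genes of amino acid breakdown and of glucose production were also lower as groups by camera, but not by fry in one direction (adjusted p = 0.151 for each list). In the list of amino acid catabolism and the urea cycle 43 of 49 genes were negative, with a median of -0.83 and 2 past the edgeR threshold (camera adjusted p = 3.69e-08; adjusted p = 0.517 with an estimated correlation, and 1.99e-12 to 0.517 over the alternatives). These were MMUT, the methylmalonyl-CoA mutase gene, at -1.71 ± 0.29 (159 ± 24.2 against 48.7 ± 11.7 CPM) and BCKDHA, a subunit of the branched-chain keto acid dehydrogenase, at -1.53 ± 0.30. The call of BCKDHA was lost with RLE factors (0.0525), upper-quartile factors (0.0571), limma-voom (0.0525), abundant genes left out (0.0543) and thinning (0.0637). In the gluconeogenesis list 15 of 17 genes were negative, with a median of -0.82 (camera adjusted p = 2.37e-04; adjusted p = 0.517 with an estimated correlation, and 1.16e-05 to 0.517 over the alternatives). Its members past the threshold were PPARGC1A and GPT (ENSDARG00000019541), an alanine aminotransferase gene, which fell by 2.46 ± 0.39, from 1662 ± 239 to 302 ± 128 CPM. PCK1, the gene of the enzyme that commits carbon to glucose, had -1.56 ± 0.80 and did not pass. Both lists shifted by -0.36 in cryo replicate 1 and by more than 1 in cryo replicates 2 and 3, the libraries that also held vitellogenin RNA.

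The list of growth hormone, insulin and IGF signalling had 3 of 31 genes past the threshold, all lower, and a median of -0.54 (camera adjusted p = 7.55e-04; adjusted p = 0.517 with an estimated correlation, and 2.26e-05 to 0.517 over the alternatives). IGF1, the growth factor that liver releases into blood, fell from 169 ± 32.3 to 41.9 ± 10.2 CPM, a log2 change of -2.01 ± 0.30 (edgeR adjusted p = 0.0232). IGFBP5 (ENSDARG00000025348) changed by -1.99 ± 0.27, and eif4ebp1, a repressor of translation initiation, by -6.31 ± 0.62, from 10.9 ± 2.42 to 0.138 ± 0.142 CPM. IRS2 (ENSDARG00000075282) had -2.96 ± 0.61 without passing. In the xenobiotic metabolism list, 3 of 49 genes passed, all lower: the glutathione transferase gene gstt1b at -6.55 ± 0.45, and the glucuronosyltransferase genes ugt5a1 at -3.15 ± 0.45 and ugt2a6 with 2 counts in the cryo group (ratio 36.9). That list's median was -0.38 (camera adjusted p = 0.0173; adjusted p = 0.53 with an estimated correlation, and 0.0178 to 0.53 over the alternatives). It missed the threshold without fresh replicate 2 (0.168), fresh replicate 3 (0.166), cryo replicate 1 (0.101) or cryo replicate 2 (0.138).

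Genes of pancreatic digestive enzymes had the largest median change of the tested lists. Of 26 tested members of the pancreas list 25 were positive, with a median log2 change of 2.70 and 11 past the edgeR threshold, all higher (22 adjusted over the list alone; camera adjusted p = 2.26e-14). With an estimated correlation the adjusted p was 0.517, and it ranged from 7.98e-19 to 0.517 over the alternatives. The amylase gene amy2a rose from 32.6 ± 1.76 to 186 ± 56.9 CPM (log2 2.51 ± 0.30, adjusted p = 0.0109), the bile salt lipase gene CEL (ENSDARG00000017490) by 2.85 ± 0.34, and the elastase genes ela3l and cela1.3 by 3.25 ± 0.52 and 3.06 ± 0.45. The trypsin gene prss1 had 2.53 ± 0.57 and did not pass. The 21 exocrine genes summed to 828, 776 and 470 CPM in the fresh libraries and to 4046, 1559 and 5233 CPM in cryo replicates 1, 2 and 3. Pancreatic tissue in the dissected liver stays open as the source of this RNA, as set out with the islet hormone genes below.

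Markers of macrophages, neutrophils and antigen presentation were higher as groups by camera. By fry in one direction none of these lists passed (adjusted p = 0.151, 0.178 and 0.151). The macrophage shift was 0.52, -0.55 and 0.03 in fresh replicates 1, 2 and 3. In cryo replicates 1, 2 and 3 it was 0.66, 1.11 and 1.02. Neutrophil shifts overlapped, with 0.36 in fresh replicate 1 and 0.33 in cryo replicate 3. Those of antigen presentation did not, at 0.33 or less in fresh and 0.62 or more in cryo libraries. The macrophage list had a median of 1.41 over 19 genes, 2 of them past the threshold. Both were among 8 genes listed as MFAP4 (ENSDARG00000090783 at 3.09 ± 0.56 and ENSDARG00000038681 at 2.55 ± 0.48). A further copy, ENSDARG00000089667, had 2.47 ± 0.55 and did not pass. Reads may be split between such near copies, which makes each value uncertain. Tested copies also count as separate members of the list, which the preset correlation of 0.01 treats as nearly independent. The macrophage list's camera adjusted p was 2.37e-04 (adjusted p = 0.517 with an estimated correlation, and 6.08e-06 to 0.517 over the alternatives). In antigen presentation 23 of 25 genes were positive, with a median of 0.97 (camera adjusted p = 3.29e-05; adjusted p = 0.517 with an estimated correlation, and 2.05e-06 to 0.517 over the alternatives). The invariant chain genes cd74a and cd74b rose by 1.87 ± 0.34 each, cd74a from 66.6 ± 17.7 to 243 ± 71.1 CPM. The cathepsin gene ctss2.2, a member of both lists, had -2.23 ± 0.44 and did not pass (adjusted p = 0.0503). With cryo replicate 1 as the single cryo library, neither list passed, at camera adjusted p of 0.0651 for macrophages and 0.101 for antigen presentation.

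The inflammatory and NF-kB list had a median of 1.08 with 0 of 21 genes past the threshold (camera adjusted p = 0.00127; adjusted p = 0.517 with an estimated correlation, and 6.62e-05 to 0.517 over the alternatives), and irg1l had the smallest p, at 5.86 ± 1.36. Neutrophil markers had a median of 0.81 over 8 genes (camera adjusted p = 0.0208; adjusted p = 0.517 with an estimated correlation, and 0.00104 to 0.517 over the alternatives), and missed the threshold without fresh replicate 2 (0.0832), cryo replicate 1 (0.0872) or cryo replicate 2 (0.182). Complement and acute phase genes had a median of 0.47 (camera adjusted p = 0.00834; adjusted p = 0.64 with an estimated correlation, and 6.30e-04 to 0.64 over the alternatives), and 0.214 without cryo replicate 1. Within that list the factor B-like gene cfbl rose by 2.21 ± 0.41 (adjusted p = 0.0637 after thinning), and hamp, which encodes the iron hormone hepcidin, fell from 298 ± 139 to 22.3 ± 12.1 CPM (-3.73 ± 0.58, edgeR adjusted p = 0.0251). Stellate cell and fibroblast markers had a median of 0.78 with POSTN (ENSDARG00000104267), an extracellular matrix gene, past the threshold at 3.08 ± 0.40. The list's camera adjusted p was 0.0369 (adjusted p = 0.807 with an estimated correlation, and 1.57e-05 to 0.807 over the alternatives), its shift was 1.37, 0.06 and -0.01 in cryo replicates 1, 2 and 3, and it was lost without cryo replicate 1 (0.562) or fresh replicate 2 (0.0869), with a filter of 1 CPM (0.0867) and after thinning (0.0585).

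Genes of cholesterol synthesis and of the cytosolic ribosome were higher in cryo replicates 2 and 3 and not in cryo replicate 1. The cholesterol list shifted by -0.17, 1.92 and 2.38 in cryo replicates 1, 2 and 3, with a median of 1.78 and 0 of 25 genes past the threshold (14 adjusted over the list alone; camera adjusted p = 8.07e-05; adjusted p = 0.64 with an estimated correlation, and 3.06e-10 to 0.841 over the alternatives). SQLE (ENSDARG00000079946), the squalene epoxidase gene, had 0.06, 24.54 and 44.52 CPM in cryo replicates 1, 2 and 3 and at most 0.71 in fresh libraries. The ribosomal list shifted by -0.16, 1.49 and 1.19, with 72 of 77 genes positive (camera adjusted p = 5.09e-11; adjusted p = 0.64 with an estimated correlation, and 1.84e-27 to 0.64 over the alternatives). Its single member past the threshold, RPL12, was lower, at -2.72 ± 0.52. With cryo replicates 2 and 3 left out together, which leaves cryo replicate 1 as the single cryo library and the spread to the fresh ones, both lists turned downward without passing, at adjusted p of 0.841 and 0.34. Cell cycle genes had a median of 0.91 with 0 of 15 past the threshold (camera adjusted p = 0.0208; adjusted p = 0.517 with an estimated correlation, and 0.00938 to 0.517 over the alternatives), and missed it without fresh replicate 2 (0.0847), cryo replicate 3 (0.108) or both cryo replicates 2 and 3 (0.177), with a filter of 1 CPM (0.063) and after thinning (0.185).

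Vitellogenins, the egg yolk precursors that the liver makes under oestrogen, took 17.4% of all counts in cryo replicate 2 and 12.4% in cryo replicate 3, and 18 to 102 counts in each of the other 4 libraries. The gene vtg1 had 948170 and 1121519 counts in cryo replicates 2 and 3, 1 in cryo replicate 1 and 0, 2 and 0 in the fresh libraries. Because the low-count filter asks for expression in 3 libraries, vtg1 and most vitellogenins were not among the tested genes. The oestrogen receptor gene ESR1 had 107.54 and 77.04 CPM in the same cryo libraries and at most 2.45 elsewhere, a log2 change of 5.89 ± 1.63 that did not pass (edgeR adjusted p = 0.109). Without the filter vtg1 and ESR1 passed, at adjusted p of 0.00523 and 0.0187, and by DESeq2 at 7.56e-08 and 0.00922. With 1 library left out and the filter kept, vtg1 was tested in 4 of 6 fits: it missed the threshold without fresh replicates 1, 2 and 3 (0.18, 0.23 and 0.241) and passed without cryo replicate 1 (3.05e-04).

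**Figure D2:**
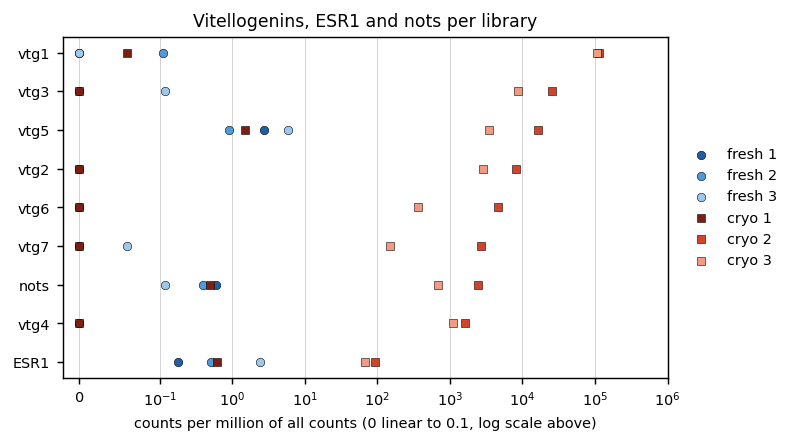
CPM of all counts (x axis, linear to 0.1 and log above) of vitellogenins, ESR1 and nots (chosen after its values were seen) in each library. Circles are fresh libraries and squares cryo libraries. Cryo replicates 2 and 3 hold 948170 and 1121519 counts of vtg1, and the other 4 libraries hold 0 to 2.

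Lists of stress and of apolipoprotein genes went down with no single gene past the threshold. Heat shock genes had a median of -0.33 with 0 of 20 past it (5 lower adjusted over the list alone; camera adjusted p = 0.00295; adjusted p = 0.517 with an estimated correlation, and 0.00159 to 0.517 over the alternatives). Immediate early genes had a median of -0.65 with 0 of 25 past it (camera adjusted p = 0.00295, 0.62 with an estimated correlation, and 2.02e-07 to 0.62 over the alternatives). The shift of that list was 0.86, -1.02 and 0.17 in fresh replicates 1, 2 and 3. In cryo replicates 1, 2 and 3 it was -0.92, -1.26 and -1.19. Apolipoprotein and lipid transport genes had a median of -0.72 with 0 of 26 past the threshold (camera adjusted p = 0.00834; adjusted p = 0.517 with an estimated correlation, and 0.00132 to 0.517 over the alternatives). The apolipoprotein gene apoeb had 3704 ± 122 CPM in the fresh and 750 ± 675 CPM in the cryo group and did not pass (edgeR adjusted p = 0.158).

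Lists tied to DNA damage and chromatin did not pass the camera test. The adjusted p was 0.169 for p53 targets, 0.825 for DNA repair, 0.493 for DNA methylation and chromatin regulators, and 0.999 for apoptosis. By fry for change in either direction they passed, at 0.0474, 0.0172, 1.34e-04 and 0.00189, as did 33 of the 42 lists in all. In the chromatin list 2 of 68 genes passed the edgeR threshold, both lower (TET1 and HDAC10, given below), where 1.98% of all tested genes passed. Of genes named beforehand, DNMT1 had a log2 change of -0.39 ± 0.30, tet3 -0.49 ± 0.31 and the 2 genes listed as DNMT3A 1.41 ± 0.44 (ENSDARG00000015566) and 0.24 ± 0.52 (ENSDARG00000005394), none past the threshold. The hepatocyte marker fabp10a had -0.25 ± 0.63, CYP1A1 -0.37 ± 0.31, CYP7A1, the rate-limiting enzyme gene of bile acid synthesis, -0.71 ± 0.90, HSPA5 -0.53 ± 0.85, FASN -1.10 ± 0.26 and IGFBP1 -1.51 ± 0.79, also without passing. The genes hsp70.1 and cdkn1a were too low to be tested. Among the most abundant transcripts, the transferrin gene tfa had 29985 ± 10103 CPM in the fresh and 99960 ± 24849 CPM in the cryo group (edgeR adjusted p = 0.14), and apoa2 36085 ± 3025 against 16240 ± 7724 CPM (adjusted p = 0.264).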

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

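The tests in this part, and the gene nots, were chosen after the results were seen, except the counts of other splits of the libraries.

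Vitellogenin RNA, largely outside the tested genes, made up 17.4% of counts in cryo replicate 2 (95% exact binomial interval 17.39 to 17.45, which covers counting error only) and 12.4% in cryo replicate 3 (12.41 to 12.45). Both lie above the highest share among control libraries, 6.04e-04%. Ovary tissue carried over in dissection would bring egg coat transcripts, and 11 zona pellucida genes summed to at most 1.92 CPM in these libraries, beside 174193 and 124308 CPM of vitellogenin (both over all counts), which argues against it. The livers of females, or of fish exposed to oestrogen, remain a candidate source: ESR1 and nots were at least 27.5 times their highest value in the other 4 libraries. Sex is not in the labels.

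The 251 changed genes were set against explanations other than the sperm treatment. If the vitellogenin-bearing libraries were the whole cause, genes called without cryo replicate 1 and a fresh replicate should go either way between those 2. At least 75.2% went the called way, with a median change of 0.83 to 1.70 against 2.24 to 4.17 in the other cryo libraries. Genes move together and cryo replicate 1 is a single library, so this share has no measured spread. It does not decide whether the vitellogenin-bearing libraries were the whole cause. The same explanation may hold for ribosomal proteins and cholesterol synthesis, whose shifts in cryo replicate 1 were -0.16 and -0.17. Lower depth as the whole cause is argued against by thinning, after which 229 of the 251 genes were still tested and 85.6% of those passed. Thinning evened out total counts, vitellogenin included. Before it, tested genes held 83.55% and 87.52% of counts in cryo replicates 2 and 3 and at least 99.8% in the other libraries. Depth in tested genes was thus evened out only in part. Inherited variants of the parents remain open, since 75.3% of changed genes had a position and the neighbour check was void, as does the sperm treatment, which the design does not separate from the parents. Sex, as far as vitellogenin marks it, stays open with the same limit. Cryo replicate 1 was as low in vitellogenin as the fresh libraries, yet at least 75.2% of the genes called without it went the called way. These genes were called with the other cryo libraries, so larger changes there are built in by that choice. Those sizes do not bear on sex, which stays open as part of the cause.

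The real split of the libraries called 251 genes and the highest of the other 9 splits called 1. For lists the real split had 20 and the highest other, which parts fresh replicate 1 with cryo replicates 2 and 3 from the rest, had 18. In each case 1 of 10 splits gave a result as large, and 10 splits are too few for a share under 0.05.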

How the results depend on the processing

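The 2 alternatives added after seeing the data were leaving out cryo replicates 2 and 3 together, which leaves 1 cryo library assumed to vary like the fresh ones, and thinning. Where no cause is given, the cause was not tested. Of 251 genes changed (129 higher, 122 lower), other size factors, a filter of 1 CPM, limma-voom, leaving out abundant genes and thinning gave 214 to 268. No low-count filter gave 705 (405 higher, 300 lower), DESeq2 1159 (634, 525), an adjusted p under 0.01 gave 34 (17, 17) and under 0.1 gave 721 (358, 363). The replicate block gave 33 (17 higher, 16 lower), with 41 of 50 named calls lost. Once the group mean of each gene was subtracted, same-numbered libraries correlated at -0.065, -0.133 and 0.058. Differently numbered ones correlated at -0.109 to 0.161. These values show no sign that the numbers pair libraries, but with 3 libraries per group they cannot exclude it. With 1 library left out the count ran from 32 to 873 (15 to 481 higher, 17 to 392 lower). With cryo replicates 2 and 3 left out together it was 109 (67 higher, 42 lower). Lists past the threshold numbered 20, and 18 to 22 under other scaling, filter, block, thinning or with 1 library left out, but 11 with cryo replicates 2 and 3 left out, 0 with an estimated correlation, 2 by fry in one direction and 33 in either.

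Values that turned sign, none of them past the threshold among single genes: by limma-voom HBE1 ENSDARG00000089087 (-0.18), PER1 ENSDARG00000056885 (-0.007) and CYP7A1 (0.27), and with the block -0.10, -0.009 and 0.30. With 1 library left out, values ran from -0.52 to 0.52 for that PER1, -1.32 to 0.21 for HSPA5, -1.18 to 1.29 for CYP7A1, -0.57 to 0.34 for HBE1 ENSDARG00000069734, -0.13 to 1.06 for ENSDARG00000097238, -0.47 to 0.79 for ENSDARG00000089087, -0.34 to 0.63 for DNMT3A ENSDARG00000005394 and -1.14 to 0.21 for fabp10a. With cryo replicates 2 and 3 left out, ESR1 was -0.63, PER1 -0.28, fabp10a 0.73, SQLE -1.92 and RPS12 -0.22, and the adjusted p of the cholesterol and ribosomal lists was 0.841 and 0.34. After thinning PER1 was -0.18. Depth limits genes near the floor: thinning left 229 of the 251 genes tested, and 196 were called.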

Other observations

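The test of the pancreas pattern was chosen after the result was seen, and the genes of the next 2 paragraphs, except hamp, were also chosen after their values were seen.

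Further single genes changed in lists that did not pass the camera test. SLC40A1, which encodes the iron exporter ferroportin, was 4.22 ± 0.71 higher on the log2 scale (edgeR adjusted p = 0.0315), with 523.15, 354.41 and 77.60 CPM in the cryo libraries and 10.89 to 23.63 in the fresh ones, while hamp, whose product removes ferroportin from the cell surface, was lower. In fatty acid synthesis ACLY, the ATP citrate lyase gene, changed by -3.57 ± 0.49 and the elongase gene ELOVL6 by -5.99 ± 1.11. The glutathione peroxidase gene gpx1a changed by 3.95 ± 0.60 and gpx3 by -1.87 ± 0.30. FGF19 changed by 5.13 ± 0.80, the cholesterol hydroxylase gene cyp46a1.1 by 3.05 ± 0.58, the demethylase gene TET1 by -3.39 ± 0.63 and the deacetylase gene HDAC10 by -1.77 ± 0.30. The camera adjusted p of their lists was 0.825 for iron and haem, 0.107 for fatty acid synthesis, 0.277 for antioxidant genes, 0.757 for bile acids and 0.493 for chromatin.

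The remaining lists did not pass either. Of 8 tested aryl hydrocarbon receptor targets 2 were past the edgeR threshold, both higher: the sulfotransferase gene sult6b1 at 3.85 ± 0.54 and the receptor gene ahr1a at 5.49 ± 0.87. In the coagulation list F9 was lower, at -1.95 ± 0.26, and 1 of 20 glycolysis genes was higher. The camera adjusted p was 0.535 for glycolysis, 0.577 for aryl hydrocarbon receptor targets, 0.757 for the unfolded protein response, 0.999 for coagulation and for interferon response, 0.162 for the proteasome, 0.319 for the circadian clock and 0.451 for glucocorticoid targets. Among cell types it was 0.303 for hepatocytes, 0.605 for cholangiocytes, 0.169 for red blood cells, 0.319 for T and NK cells, 0.751 for endothelial cells and 0.169 for intestine. Lists of vitellogenesis, B cells, ovary and testis had 2, 3, 1 and 1 tested genes and were not tested.

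All-or-none genes were counted as those at 5 CPM or more in every library of a group and under 0.3 in every library of the other. The real split gave 16 (6 higher and 10 lower, among them PHF21A, cbr1l and pof1b), and the other 9 splits at most 1. No prediction was written for this count. It restates the near-silent genes among the largest changes above, so it is no separate support for them.

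For the higher digestive enzyme RNA, an equal rise of every other cell type is argued against. The next highest median among cell type lists was 1.41, beside 2.70 for the pancreas, and endothelial cells and cholangiocytes had 0.09 and 0.17. An unequal rise is not argued against, since macrophage, neutrophil and stellate cell lists also passed upward, at medians of 1.41, 0.81 and 0.78. Pancreatic tissue in the dissected liver, expression of these enzymes by liver cells and an effect of the sperm treatment stay open. Chosen after their values were seen, PLA2G1B, the list member that was lower, had 67.86, 44.98 and 83.37 CPM in the cryo and 96.66 to 109.77 in the fresh libraries. The islet hormone genes sst2, gcga, GCG and ins, also chosen after their values were seen, stood together at 88.43, 58.35, 15.53 and 9.64 CPM in cryo replicate 1 and at 10.88, 3.77, 2 and 0.78 in cryo replicate 3, above each fresh library, where they reached 4.19, 2.78, 1.58 and 0.65 in fresh replicate 2. In cryo replicate 2, whose exocrine sum was 1559 CPM, gcga had 0.14 and the other 3 had 0. Hormone RNA rising with enzyme RNA is what pancreatic tissue would bring to cryo replicates 1 and 3, but cryo replicate 2 had the enzymes without the hormones, so these values do not decide the source.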
